A study of Mus musculus with 6 samples.

How the data were processed

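Total RNA from lenses of 2-month-old mice was profiled by RNA sequencing in 6 libraries, each made from 2 lenses. The groups come from the sample titles: 3 wild-type libraries (WT, strain C57BL/6) and 3 libraries from fibronectin conditional knockout mice (FNcKO, mixed strain background). The labels describe the 3 samples of each genotype as biological replicates. Per the labels' protocols, lenses were microdissected and frozen, and libraries were made with a stranded total RNA kit for very small inputs, which keeps non-coding RNA as well as messenger RNA.

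The values are FPKM (fragments scaled to transcript length and to the fragments of the library), which the authors computed and deposited as 1 table with a column for each library. Per the submitters' processing notes, FastQC, cutadapt 1.12, TopHat2 2.1.0 and Cuffdiff 2.2.1 were used, and the builds mm10 and GRCm38.p5 are named. The order of the steps, the gene annotation, the treatment of fragments that map to several places, any scaling between libraries and the use of strand in counting are not given in the sources used here. Without the use of strand being stated, overlapping and antisense genes cannot be told apart, and values of near-identical paralogs are uncertain. The table has 41449 rows, each with a symbol and a position. Start positions were raised by 1 to count from 1, because the start of Fn1 lay 1 base before that in the RefSeq table of the same assembly.

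WT replicate 2 has no value in 3578 rows (8.63%), which are the end of the table: chromosome 9 from position 51213690, chromosome X, and everything listed after them. Genes in these rows were tested on the 5 other libraries, and n is given as 2 for WT. In 27 rows the symbol had been turned into a date, and 1 value of WT replicate 3 was unreadable and was treated as missing.

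From the deposited FPKM values, log2(FPKM + 1) was computed for the 10149 genes with a mean of at least 1 FPKM, of which 742 had no value in WT replicate 2. Genotypes were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, while folds are ratios of mean FPKM. A stricter count required also an absolute log2 change of at least 1 and a difference of means of at least 2 FPKM. Strain could not be a term of the model, because it divides the libraries exactly as genotype does.

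Gene lists were compared with the other genes by camera with a preset correlation of 0.01, for lists with at least 5 members that had a value in every library. Each list was also tested with a correlation estimated from the data and with fry. Calls within 10 Mb of Fn1 were compared with calls elsewhere by Fisher's exact test. Single values, such as the share of FPKM in crystallins, were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1.

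The groups, the tests, the gene lists, the alternatives and the rule for naming genes were set before the data were examined. The rule named Fn1; the 12 largest higher and 12 largest lower log2 changes among genes past the stricter count whose groups did not overlap, leaving out predicted genes, pseudogenes and small RNAs recognised by the start of their symbol; the members of each list past the test, at most 4, or the 2 with the smallest p; and the 2 most abundant members of each cell type list. Transfer RNA rows passed the rule because their symbols were not among those left out. Some genes that the rule takes are not reported here. Other genes are named as chosen after their values were seen.

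Fragment numbers are not in the table. Depth was estimated from single-exon genes, whose low values are multiples of what 1 fragment is worth. Depths were searched for the closest match to whole numbers, and a simple fraction of the best depth was taken where it matched nearly as well. This gave 32700000, 28700000 and 26800000 fragments for WT replicates 1 to 3, and 21800000, 21600000 and 19700000 for FNcKO replicates 1 to 3. Between 59.7% and 68.5% of the values used lay within 0.15 of a whole number. At a depth fixed beforehand 30% would by chance, while the search itself raises this share. These depths describe the libraries and enter no test of genes or lists. They were used for the fragment numbers of Fn1 and for the scan of transfer RNA rows described at the end.

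The comparison was tested on simulated data built from 9407 real genes, with 200 genes changed. Each gene was given the average spread within groups of genes of similar level, with independent normal noise. It recovered 31.3% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 97% of those changed 4-fold, with 11 false calls. With no gene changed it made 0 calls. Differences in spread between genes of similar level were left out, so these figures describe a simpler setting than the real data.

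Alternatives covered the pseudocount, the filter on low values, the scaling between libraries, the variance model, sample weights, a replicate block, each library left out in turn, the list tests and the window around Fn1. The fits on genes with a value in every library and without genes within 10 Mb of Fn1 were added after the data had been seen.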

Results

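Fibronectin is a glycoprotein of the extracellular matrix that cells bind through integrins. The series asks what it does in the lens after birth. Gene expression was measured by RNA sequencing in lenses of 2-month-old mice, in 3 WT libraries and 3 FNcKO libraries of 2 lenses each. The estimated depth was 26800000 to 32700000 fragments in WT and 19700000 to 21800000 in FNcKO. WT mice were C57BL/6 and FNcKO mice were of mixed background, so every difference below is between genotypes and strain backgrounds together.

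Fn1, the targeted gene (chromosome 1, 71585473 to 71653234, GRCm38), was low in both genotypes. It stood at 0.135, 0.188 and 0.253 FPKM in WT replicates 1 to 3 and at 0.128, 0.0482 and 0.0942 FPKM in FNcKO replicates 1 to 3. The means were 0.192 ± 0.0592 FPKM (SD, n = 3) and 0.09 ± 0.0399 FPKM (SD, n = 3), 2.13-fold lower in FNcKO, and every FNcKO value lay below every WT value. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. In the limma fit, to which Fn1 was added although it lay below the filter of 1 FPKM, the log2 change was -0.13 (SE 0.14, adjusted p = 0.686), and it was 0.26 after quantile normalization. With the depths estimated here and its longest annotated transcript (8315 nucleotides), these values correspond to about 35.6, 43.9 and 55 fragments in WT and 22.6, 8.4 and 15.1 in FNcKO. The value covers the whole gene and does not show whether the floxed part is present.

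**Figure D1:**
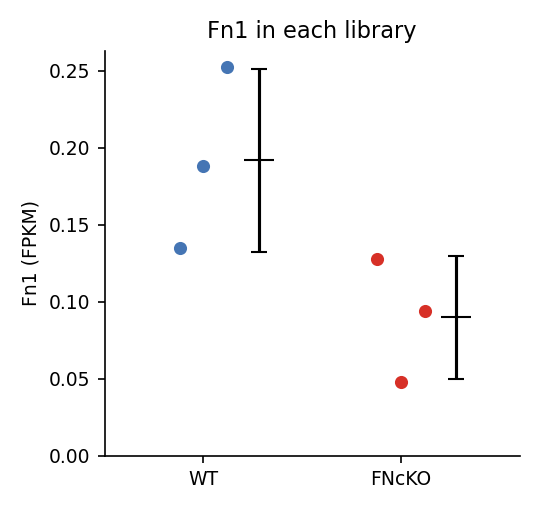
Fn1 in each library, in FPKM on a linear axis from 0. Each point is 1 library, and the bars beside them show the mean and SD of each genotype; the WT values run from 0.135 to 0.253 and the FNcKO values from 0.0482 to 0.128.

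Across the lens transcriptome, FNcKO lenses had more RNA of Clec3b (tetranectin, a plasminogen-binding lectin), Nes (nestin, an intermediate filament protein) and Tpm4 (an actin-binding tropomyosin), and less of Clic5 (an intracellular chloride channel protein linked to the actin cytoskeleton), Col6a3 (a chain of collagen VI) and Fgf1 (acidic fibroblast growth factor). Clic5 fell from 17.7 ± 0.128 to 0.0274 ± 0.0087 FPKM (SD, n = 3 each; adjusted p = 3.07e-06), which is 645-fold. Col6a3 fell from 11.6 ± 1.02 to 1.34 ± 0.274 FPKM (SD, n = 3 each; adjusted p = 0.00129). Of 10149 genes tested, 192 (1.89%) passed adjusted p 0.05, with 87 higher and 105 lower in FNcKO. Of these, 53 also passed the size rule, 25 higher and 28 lower. In limma, 1839 of the 10149 genes tested had an unadjusted p under 0.05, where 507.5 would by chance. Counts at that threshold in the lists below, and counts adjusted over a list alone, are to be read against this share.

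Among the largest rises, Lims2, an adaptor of the integrin-linked kinase complex, rose from 0.286 ± 0.212 to 4.62 ± 1.29 FPKM (SD, n = 3 each). Nes rose 5.99-fold, Actn2 (a sarcomeric alpha-actinin) 4.21-fold and Tpm4 2.57-fold, the last from 18.9 ± 0.666 to 48.7 ± 4.86 FPKM (SD, n = 3 each). Fndc1, which holds fibronectin type III domains, rose from 0.137 ± 0.0418 to 2.42 ± 0.859 FPKM (SD, n = 3 each). Clec3b rose from 0.804 ± 0.0762 (SD, n = 2) to 15.1 ± 2.71 FPKM (SD, n = 3), and Trex1, a DNA exonuclease, rose 2.71-fold, also without a value in WT replicate 2. Aqp1, a water channel, rose 2.96-fold, Rassf5 3.91-fold, the histone gene Hist1h2al 2.97-fold and Rida, a deaminase, 2.36-fold. LOC102238518 went from 0.0426 ± 0.0738 to 2.26 ± 0.422 FPKM (SD, n = 3 each). Adjusted p-values of these 12 genes lay between 0.00237 and 0.0432. Actn2 missed the threshold with any one library left out, and Aqp1 with any but FNcKO replicate 1. Fndc1, Trex1 and Lims2 missed it with some of the libraries left out.

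Among the largest falls, Olfml3, a secreted olfactomedin-like protein, fell from 31.6 ± 2.17 to 6.98 ± 0.524 FPKM (SD, n = 3 each; adjusted p = 0.00101). H2-T24, a gene of the major histocompatibility complex region, fell 14.5-fold, Fgf1 10.3-fold, the homeobox gene Pbx4 10.1-fold and Map2, a microtubule-associated protein, 4.33-fold. H2-T24 and Hist1h2al belong to families of similar genes, so their values are uncertain. The rule also took 5 rows of glutamine transfer RNA, which were above 0 in each WT library with a value and listed at 0 in all 3 FNcKO libraries. Of these, n-TQctg6, n-TQctg7 and the Trnaq-cug row at 21933961 on chromosome 13 held the same 3 values, 46.2, 25.8 and 55.5 FPKM, in WT replicates 1 to 3. The Trnaq-cug row at 21920200 held 46.2, 51.6 and 360.9 FPKM. These rows are 72 nucleotides long and near-identical to each other, so their values are uncertain.

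**Figure D2:**
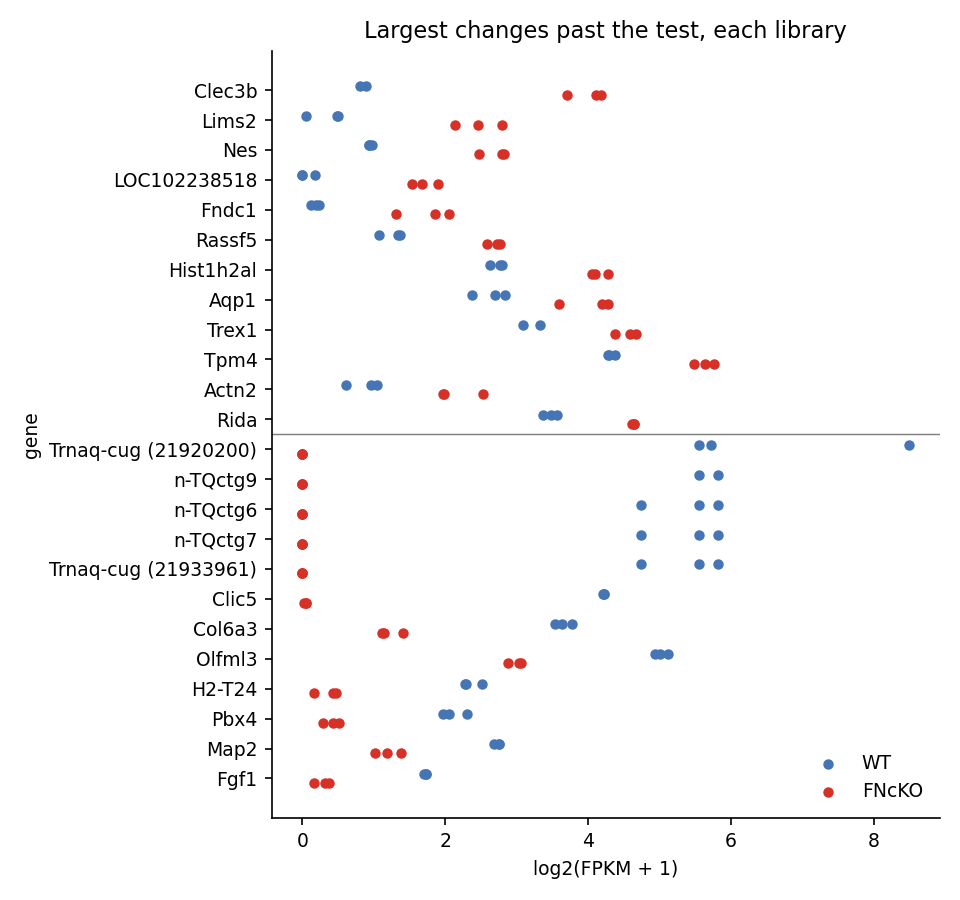
Genes with the largest log2 changes past the test and the size rule, with log2(FPKM + 1) on the horizontal axis. Each point is 1 library, blue for WT and red for FNcKO; genes above the grey line were higher in FNcKO and those under it lower, and the transfer RNA rows sit at 0 in FNcKO.

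All 192 genes had WT and FNcKO values that did not overlap, which held for 25.6% of the tested genes, where chance gives 10.7%. Among the 9407 genes with a value in every library, it held for 25.1%, where chance gives 10%; for genes without WT replicate 2, chance gives 20%. The split of higher and lower genes moved with the scaling between libraries. It was 45.3% higher as deposited, 56% with median-ratio scaling (234 genes), 60.4% after quantile normalization (197 genes), 72% with every library at the same FPKM total (93 genes) and 77% with the same total without crystallins (87 genes). The last 2 moved the median log2 change of all genes from -0.04 to 0.15 and 0.29. Without one library the count was 48 (WT replicate 1), 55 (WT replicate 2), 55 (WT replicate 3), 111 (FNcKO replicate 1), 79 (FNcKO replicate 2) or 64 (FNcKO replicate 3). Of the 39 calls among the genes named by the rule, between 18 and 24 were kept without one library.

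Crystallins, the structural proteins of the lens fiber cell, were the 1 list of 18 that passed camera (adjusted p = 7.36e-06; adjusted p = 0.797 with an estimated correlation). Of 16 crystallins tested, 2 rose and none fell: Cryge (chromosome 1, 65048557 to 65051163) from 22490 ± 944.8 to 43150 ± 4667 FPKM (SD, n = 3 each; adjusted p = 0.0331) and Cryga (65100389 to 65103363) from 3590 ± 618.7 to 8020 ± 1266 FPKM (SD, n = 3 each; adjusted p = 0.0422). Adjusted over the list alone, 4 rose. The list's median log2 change was 0.24, and it stayed above 0 under each of the 4 other scalings, between 0.28 and 0.67. After quantile normalization the list no longer passed camera (adjusted p = 0.228), Cryge stood at limma adjusted p = 0.0651 and Cryga also missed the threshold. Neither Cryge (adjusted p from 0.0557 to 0.156) nor Cryga (0.0677 to 0.158) passed with any one library left out. Crybb2, the most abundant, stood at 96930 ± 2013 in WT and 90090 ± 4021 FPKM in FNcKO (SD, n = 3 each; adjusted p = 0.695), and Crygb at 37930 ± 1595 and 48950 ± 2445 FPKM (SD, n = 3 each; adjusted p = 0.18). The gamma crystallin genes are near-identical, so the division of fragments among them is uncertain.

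**Figure D3:**
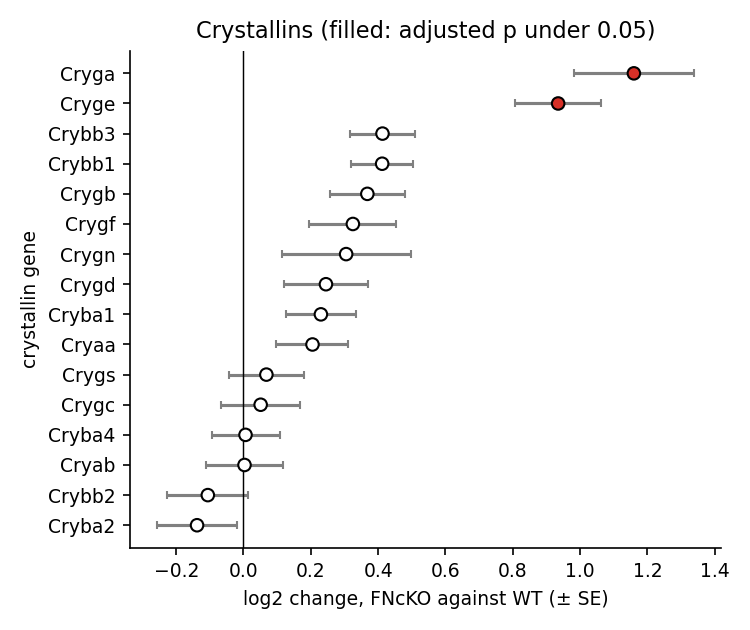
Log2 change of each crystallin gene in FNcKO against WT, with its SE as bars. Filled points mark adjusted p under 0.05: Cryga at 1.16 and Cryge at 0.94 on the log2 scale.

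Of the FPKM in rows with a value in every library, the crystallins took 23.9% ± 1.13 in WT and 32.5% ± 4.18 in FNcKO (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). A single row, LOC108167755 on chromosome 1, took 21.1% ± 4.68 in WT and 18.2% ± 1.24 in FNcKO (SD, n = 3 each, exact permutation p = 0.5). Summed crystallin FPKM rose less than the share, from 402400 in WT to 458600 in FNcKO, 1.14 times as high. The total over rows with a value in every library ran from 1631866 to 1725738 FPKM in WT. It was lower in FNcKO, from 1251386 to 1519627 FPKM.

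Of 27 fiber cell genes, 1 rose, also adjusted over the list alone, with 9 at an unadjusted p under 0.05: Caprin2, an RNA-binding protein, 1.53-fold (adjusted p = 0.0204). The fiber list did not pass camera as deposited (adjusted p = 0.108, or 0.797 with an estimated correlation). At the preset correlation it passed after quantile normalization, where it was the only list to pass, with both same-total scalings and without WT replicate 2. Bfsp1, a beaded filament protein, stood at 3972 ± 106.4 and 4031 ± 181.7 FPKM and Lenep at 4666 ± 212 and 4330 ± 162.7 FPKM in WT and FNcKO (SD, n = 3 each). Of 20 epithelial genes, 2 rose, the amino acid transporter Slc7a5 (1.49-fold) and the receptor tyrosine kinase Epha2 (1.45-fold); adjusted over the list alone, 2 rose and 1 fell. Caprin2, Slc7a5 and Epha2 missed the threshold with both same-total scalings (adjusted p from 0.0502 to 0.101). With the total taken without crystallins their log2 changes grew from 0.60, 0.52 and 0.47 to 1.01, 0.90 and 0.84, while their SEs went from between 0.053 and 0.072 to between 0.171 and 0.196. Caprin2 and Epha2 missed the threshold with any single library left out, and Slc7a5 with any but FNcKO replicate 1. The abundant Cd24a and Igfbp7 had adjusted p = 0.161 and 0.938.

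Fibronectin receptors and adhesion genes had 0 of 19 past limma's test over all genes. Other listed members, such as Itga5, Itga4, Itga8 and Itgb3, lay below the filter and were not tested. Outside the list, Lims2 passed, as did Cd44 and Itgb1bp1, which were chosen after their values were seen. Cd44 fell 1.54-fold and Itgb1bp1 1.61-fold (limma adjusted p = 0.018 and 0.0328). Of the 19 tested members, 3 had an unadjusted p under 0.05, against 1839 of all 10149 genes tested. Adjusted over the list alone, 1 rose and 2 fell. Sdc2, a syndecan, stood at 16.1 ± 1.24 in WT and 11.4 ± 0.872 FPKM in FNcKO (SD, n = 3 each; adjusted p = 0.0682), and Lims1, an adaptor related to Lims2, at 5.77 ± 0.356 and 8.07 ± 0.915 FPKM (SD, n = 3 each; adjusted p = 0.0964). Of 19 basement membrane genes, which include those of the lens capsule, Frem2 fell 2-fold (adjusted p = 0.0458, and from 0.0572 to 0.218 under the 4 other scalings), while adjusted over the list alone 3 rose and 2 fell. Frem2 passed with FNcKO replicate 1 left out and missed the threshold with any other library left out. Of 17 interstitial matrix genes, Fndc1 rose and Col6a3 fell, and adjusted over the list alone 4 rose and 2 fell. In the same libraries all 5 tested markers of the ciliary body and iris, which lie beside the lens, had log2 changes above 0 (median 0.63).

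Signalling lists held 1 or 2 calls each. In the TGF-beta and fibrosis list of 24 genes, Bmp7 rose 1.71-fold and Inhba, an activin subunit, fell 1.61-fold; adjusted over the list alone, 1 rose and 4 fell. Fgf1 was the only call among 10 FGF genes (1 rose and 1 fell adjusted over the list alone), and Fzd6, a Wnt receptor of planar polarity, fell 1.54-fold as the only call among 14 Wnt genes, with 1 lower adjusted over the list alone. Atf4, the transcription factor of the integrated stress response, rose 1.53-fold among 17 stress response genes, with 1 higher adjusted over the list alone. Among 26 antioxidant genes, 3 fell: the cystine transporter Slc7a11 (1.68-fold), Prdx6 (1.53-fold) and Sod1 (from 178.4 ± 10.4 to 121.1 ± 10.2 FPKM, SD, n = 3 each); adjusted over the list alone, 1 rose and 4 fell. Dhcr7 rose 1.39-fold among 21 cholesterol synthesis genes, with 2 higher adjusted over the list alone. With both same-total scalings Bmp7, Inhba, Fzd6, Slc7a11, Prdx6, Sod1 and Dhcr7 missed the threshold; with the total taken without crystallins Atf4 did too, and the log2 changes of Sod1 and Prdx6 went from -0.56 and -0.57 to -0.13 and -0.17, of Slc7a11 and Inhba from -0.58 and -0.61 to -0.24 and -0.22, and of Fzd6 from -0.45 to -0.14. Under that scaling the log2 changes of Bmp7, Dhcr7 and Atf4 grew from 0.58, 0.40 and 0.60 to 0.91, 0.76 and 1.01, while their SEs went from between 0.057 and 0.079 to between 0.164 and 0.187. Prdx6 and Sod1 also missed it with median-ratio scaling (adjusted p = 0.0536 and 0.0742), and Prdx6 after quantile normalization (0.0593). Bmp7, Fzd6, Atf4, Slc7a11, Sod1 and Dhcr7 missed the threshold with any single library left out. Inhba passed with WT replicate 2 left out and Prdx6 with FNcKO replicate 1 left out. Both missed it with any other library left out. None of these lists passed camera, nor did any other list but the crystallins (adjusted p from 0.108 to 0.939).

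Of 52 nuclear genes of oxidative phosphorylation, 0 passed limma's test and 0 adjusted over the list alone, with 7 at an unadjusted p under 0.05. Of the 52, 40 had log2 changes under 0, with a median of -0.09 (camera adjusted p = 0.108). That median was -0.05 with median-ratio scaling, and 0.16, 0.32 and 0.01 with the same FPKM total, the same total without crystallins and quantile normalization. Without the filter on low values the list passed camera, as did the interstitial matrix, crystallin, and ciliary body and iris lists. Of 10 cell cycle genes, 0 passed limma's test, adjusted over the list alone or unadjusted at 0.05, with Pcna at adjusted p = 0.317 and Mcm2 at 0.472. Only 2 immediate early and 4 interferon response genes were above the filter, and 0 passed limma's test or were called adjusted over the list alone, with 0 and 1 at an unadjusted p under 0.05; Jun stood at 4.62 ± 0.207 and 4.6 ± 0.232 FPKM and Irf9 at 0.98 ± 0.139 and 1.09 ± 0.289 FPKM in WT and FNcKO (SD, n = 3 each).

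Of the photoreceptor, pigment cell, and ciliary body and iris markers, Gnat1 and Aqp1 passed the test. Rod genes made up most of the 13 tested photoreceptor genes, of which 12 had log2 changes under 0 (median -0.42) and Gnat1, rod transducin, fell from 20.6 ± 2.34 (SD, n = 2) to 9.42 ± 0.503 FPKM (SD, n = 3; adjusted p = 0.0215), the 1 call also adjusted over the list alone. Gnat1 passed without WT replicate 2, where it has no value, and missed with any other library left out (adjusted p from 0.0569 to 0.0954). Of 5 pigment cell genes, 0 passed limma's test over all genes, 3 had an unadjusted p under 0.05 and 3 fell adjusted over the list alone, with Ttr at 8.85 ± 2.87 and 3.68 ± 0.756 FPKM (SD, n = 3 each; adjusted p = 0.0887) and Oca2 at adjusted p = 0.0798. All 5 ciliary body and iris genes had log2 changes above 0 (median 0.63), with Aqp1 past the test, 3 adjusted over the list alone, and Optc, opticin, at 18.2 ± 3.58 and 42.9 ± 9.93 FPKM (SD, n = 3 each; adjusted p = 0.0682). The photoreceptor and pigment medians stayed under 0 and the ciliary median above 0 under the 4 other scalings. The photoreceptor, pigment and neuron lists did not pass camera (adjusted p = 0.203, 0.108 and 0.203). With an estimated correlation, camera gave each of them adjusted p = 0.797 on the values as deposited. At the preset correlation all 3 passed without WT replicate 2, when 6 lists did, and with both same-total scalings, under which Gnat1 missed the threshold.

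Of 6 neuron and glia genes, Map2 alone fell, also adjusted over the list alone; Glul stood at adjusted p = 0.569. Aldh3a1 (28.2 ± 2.54 and 32.7 ± 16.6 FPKM, SD, n = 3 each), Bpgm (adjusted p = 0.947) and Egfl7 (adjusted p = 0.292) were the only tested members of the corneal, red blood cell and endothelial lists, and 0 of 18 macrophage and leukocyte genes reached the filter. Of 6 genes known to differ between inbred strains, 0 passed limma's test, adjusted over the list alone or unadjusted at 0.05. Bfsp2, of which some strains carry a deletion, stood at 2041 ± 58.1 (SD, n = 2) in WT and 2280 ± 49.2 FPKM (SD, n = 3) in FNcKO, and Pde6b, mutated in FVB/N, at 3.91 ± 1.76 and 2.32 ± 0.292 FPKM (SD, n = 3 each; adjusted p = 0.413).

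**Figure D4:**
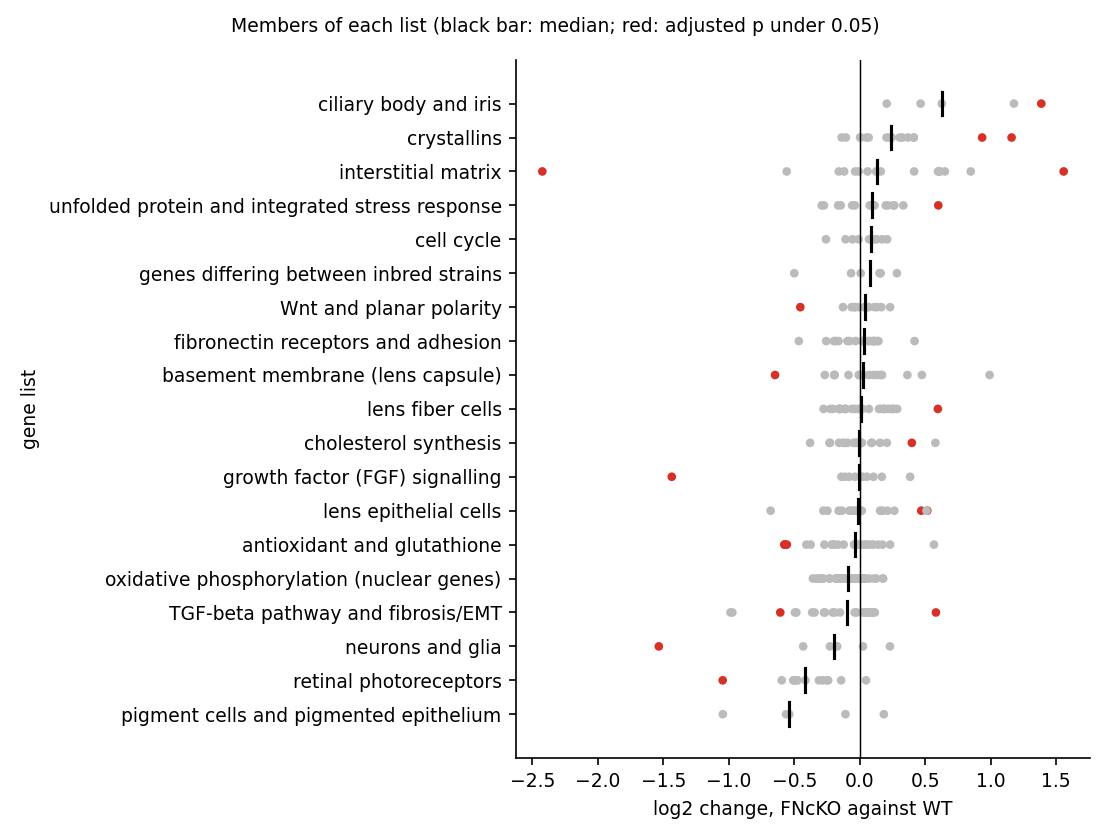
Log2 changes of the tested members of each list with at least 5 of them. Each point is 1 gene, red where its adjusted p is under 0.05, and the black bar is the list's median, which runs from -0.54 for pigment cells to 0.63 for the ciliary body and iris.

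The last comparison asked whether called genes were more frequent around Fn1, since the background of the FNcKO mice is mixed. Within 10 Mb, 4 of 68 tested genes were called (5.88%), against 188 of 10081 elsewhere (1.86%), an odds ratio of 3.29 (95% interval 0.861 to 8.98; Fisher's exact test, two-sided, p = 0.0396). They were Cryge and Cryga, 6.5 Mb before Fn1, Map2 (5.4 Mb before) and Erbb4 (3.6 Mb before), a receptor of neuregulins that rose 2.75-fold. Cryge and Cryga are neighbouring, near-identical genes, while Fisher's exact test counts each call as independent. Within 5 Mb the odds ratio was 1.37 (Fisher's exact p = 0.526). With any one library left out, the exact p was between 0.17 and 0.409 and the odds ratio between 1.94 and 3.18.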

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

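The fits on genes with a value in every library (198 genes called) and without genes within 10 Mb of Fn1 (184) were chosen after seeing the data. Without a filter on low values, 101 genes, 34 at 2-fold, and 4 lists were called, with an odds ratio near Fn1 of 1.45; at a mean of at least 5 FPKM, 34 genes passed at 2-fold. The same FPKM total gave 93 genes and 5 lists, and the same total without crystallins 87 genes and 5 lists. The ratio near Fn1 no longer passed without the filter, at a mean of at least 5 FPKM (3.42), with median-ratio scaling (2.68), robust variance (2.44, 323 genes), sample weights (3.01), quantile normalization (1.54) or 5 Mb (1.37). Leaving out small RNAs, mitochondrial genes and crystallins gave 402 genes, 0 lists and 1.65. With an estimated correlation, and with fry in one direction, 0 lists passed; fry found change in either direction in 15. Quantile normalization turned the log2 change of Fn1 to 0.26. Without 1 library, calls ranged from 48 to 111, lists from 1 to 6 and the ratio from 1.94 to 3.18; fewer libraries were tested there, and elsewhere the cause was not tested. Same-numbered samples did not deviate together (correlations -0.027, -0.055 and -0.046), so the numbers are not read as pairing. A replicate block left 14 genes called, 14 of them 2-fold, and a ratio of 0. Clic5, Col6a3, Olfml3 and Hist1h2al passed under all 21 alternatives, the replicate block included. The largest adjusted p over alternatives was 0.247 for Cryge, 0.158 for Cryga and 0.593 for Sod1. Depth was lower in FNcKO.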

Other observations

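Further genes that passed the test lie outside the naming rule and were chosen after their values were seen. Pgam2, the muscle phosphoglycerate mutase, rose from 164.2 ± 11.7 to 351.2 ± 26.3 FPKM (SD, n = 3 each; limma adjusted p = 0.0073). Chrng, a subunit of the fetal muscle acetylcholine receptor, rose 2.4-fold, Cfl2 (muscle cofilin) 1.95-fold and Fscn1 (fascin, an actin-bundling protein) 3.19-fold. Cpt1a, which admits fatty acids to mitochondria, rose 1.78-fold. Pdgfrb fell 2.22-fold and Krt19 1.95-fold, and Csrp1, a LIM domain protein, fell from 47.3 ± 0.947 to 32.8 ± 1.93 FPKM (SD, n = 3 each; adjusted p = 0.0275). These genes come from no list set beforehand, and no theme was tested for them.

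Neighbours on chromosome 18, Lims2 (31922278 to 31958619) and Myo7b (31959234 to 32036931), both rose, Myo7b by 3.35-fold (limma adjusted p = 0.00814). On chromosome 13, Serpinb6b fell 2.93-fold and its relative Serpinb6a 1.81-fold, and as paralogs they are uncertain. Gm6166, a predicted gene on chromosome 9, rose from 2163 ± 19.9 (SD, n = 2) to 13610 ± 1029 FPKM (SD, n = 3; adjusted p = 0.00237). A comparison by chromosome was not among the tests set beforehand. In it, 16 of 273 tested genes on chromosome 18 were called (5.86%, Fisher's exact test, adjusted p = 0.00119) and 6 of 818 on chromosome 2 (0.733%, Fisher's exact test, adjusted p = 0.0477). On chromosome 14, 0 of 352 were called (Fisher's exact test, adjusted p = 0.0211). There, limma gave 43 genes an unadjusted p under 0.05, against 1839 of all 10149 genes tested.

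Summed FPKM of the photoreceptor genes with a value in every library was 75.4, 32.2 and 89.1 in WT replicates 1 to 3 and 46.9, 46.5 and 45.5 in FNcKO replicates 1 to 3.

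In what follows, the tests on pairs of neighbouring genes, on the gamma crystallin sum, on one scaling factor per library, on the fiber cell list and on the transfer RNA rows were chosen only after the results were seen. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many as 192 genes, the real one, and the highest other gave 11; for the 53 genes of the 2-fold rule it was also 1 of 10, with 11 as the highest other. With 10 splits no share under 0.05 can be reached.

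Called genes lay close together on the chromosomes: 75 pairs were 100 kb to 2 Mb apart, against a mean of 47.4 in 10000 random placements (permutation p = 0.002). Random placement is thus argued against. Without pairs of similar symbol, 73 pairs stayed, against a mean of 46.3 in random placements (permutation p = 0.003). Fragments shared between genes of similar symbol are thus argued against as the whole of the excess. Duplicates under other symbols, such as the glutamine transfer RNA rows, stayed in and were not tested. Co-expressed neighbours without any difference of genotype or strain may contribute, but this could not be decided. The 192 genes of smallest p gave 45 to 103 pairs in the 9 other splits of the libraries. In 3 of these splits there were at least as many as 75. Each group in the other splits mixes both genotypes, so they are not free of a genotype difference. Of the 75 pairs, 43 moved in opposite directions and 32 in the same direction. The other splits gave 14 to 42 and 22 to 68. Random placements gave means of 23.6 opposite (permutation p = 0.001) and 23.7 same (permutation p = 0.083). The excess over random placement was thus clearer in opposite directions, while neighbours that rise and fall together would add pairs of the same direction. Blocks of another strain's chromosome in FNcKO stay open: the odds ratio near Fn1 was 3.29, with an interval that includes 1, and strain and genotype cannot be told apart in this design.

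Cryga and Cryge were higher in FNcKO, and a mere shift of fragments between near-identical gamma crystallins would leave their sum as it was, but summed Cryga to Crygf FPKM was 1.32 times as high, from 145000 ± 6933 to 190700 ± 15340 FPKM (SD, n = 3 each) with no overlap. More fiber cell RNA of every kind would raise the fiber cell list by about as much as Cryge (0.94), while its median log2 change was 0.006, with quartiles of -0.133 and 0.186, and between 0.05 and 0.43 under the 4 other scalings, each time below Cryge by more than the interquartile range. Under the 3 scalings by one factor per library, Cryge stood at 0.98, 1.19 and 1.36 on the log2 scale. The highest limma adjusted p of Cryge and Cryga there was 0.0415. These scalings alone cannot decide whether a single factor per library is the whole cause, since each raised FNcKO against WT. They moved the median log2 change of all genes from -0.042 to -0.009, 0.153 and 0.294, so none could have lowered Cryge. But a factor per library moves all genes well above the added 1 FPKM by the same log2 amount. As deposited, Cryge and Cryga stood at 0.94 and 1.16, against -0.138 to 0.413 for the 14 other crystallins. These values argue against a single factor per library as the whole cause for Cryge and Cryga. A scaling that depends on the level stays open. After quantile normalization Cryge was at 0.80 (SE 0.147) and limma adjusted p = 0.0651, against 0.94 (SE 0.128) as deposited, a smaller change with a larger error. Cryga missed the threshold there too. A genotype or strain effect on the gamma crystallin cluster, which lies near Fn1, may also account for it and was not tested.

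The glutamine transfer RNA rows were at 0 in every FNcKO library. Values that rest on 1 or 2 fragments may be the cause, but this could not be decided. Among 206 rows of the same length, 0 candidate values of 1 fragment were met in all 6 libraries within 1.5%, and the best was met in 5. The scan rests on the estimated depths, so its result depends on their accuracy. Lower recovery of all short RNAs in FNcKO libraries also stays open. The median log2 change of 77 small nucleolar RNAs was -0.849 (3 called, all lower), between the bounds set for either answer. That of 238 transfer RNAs, the glutamine rows among them, was -0.70 with 156 under 0. All 9 called small RNAs were lower. But these were the glutamine rows themselves, the same 3 small nucleolar RNAs and Mir1893, so the count is no separate support. The median of 105 microRNAs was 0.188 (quartiles -1.63 and 1.77). The small RNA share of FPKM was 20.9% ± 3.25 in WT and 20.2% ± 1.93 in FNcKO (SD, n = 3 each, exact permutation p = 1). Without the ribosomal row Rn18s-rs5 the share was 20.1% ± 3.68 and 17.9% ± 1.74. A biological difference in these RNAs was not tested.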
